A study of Mus musculus with 12 samples.

How the data were processed

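Total RNA from the kidneys of 12 male C57BL/6 mice, 10 weeks old, was measured on Illumina MouseWG-6 v2 BeadChips, single-colour expression arrays on which each transcript is read by beads that carry one probe sequence. Per the labels, 6 mice received 0.1% saline, given 2 times a day, and 6 received colistin at a daily dose of 16 mg/kg, divided over 2 doses. Exposure lasted 72 hours. The arrays lay on 2 BeadChips with 3 mice of each group on each. Saline mice held the 1st, 3rd and 5th positions of both BeadChips and colistin mice the positions between them, so array position and treatment cannot be told apart.

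The deposited probe table holds the mean bead signal of 45281 probes per array as intensities on a linear scale, per the file headers, with a detection p-value for each probe and array that sets its signal against the negative control beads of the array. These intensities had not been background-subtracted: the lowest signal of any array was 74.7. The authors also deposited a table of intensities averaged per gene symbol (30854 rows), with detection p-values per the file headers. They deposited normalized intensities per probe and per symbol. Checked on the files, the normalized intensities kept the order of the raw signals within each array (lowest Spearman rho 1), were on a linear scale, reached down to -11.85 and followed nearly 1 distribution on all arrays. The column medians of the normalized probe intensities lay between 3.39 and 3.42. Those of the normalized gene-level table lay between 3.31 and 3.62. GenomeStudio and Partek are named in the submitters' processing notes; their versions, roles and settings are not given in the sources used here.

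The raw probe intensities were background-corrected and quantile-normalized with neqc in limma 3.58.1 (R 4.3.3), which estimated the background from the detection p-values and added an offset of 16 before log2 values were taken. The offset compresses the fold changes of dim probes. Probes with a detection p under 0.01 on at least 4 of the 12 arrays were kept, whatever their group: 16179 probes of 11347 genes were kept and 29102 probes were dropped. Array symbols were brought to current symbols through the mouse reference's gene names and synonyms (GRCm38.p6, used for names only): 27760 probes carried a current symbol, 8013 matched by a synonym and 9508 kept the array's own name. Values are named by the array's symbol, with the current one where it differs. A gene's change is that of the named probe, since probes of a gene can differ. For gene lists, the kept probe with the highest mean stood for each gene.

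Groups were compared per probe with lmFit and eBayes in limma with group as the only term, two-sided, with Benjamini-Hochberg adjustment over all kept probes. A probe was called changed at an adjusted p under 0.05. Fold changes are differences of normalized log2 means, colistin minus saline, with limma's standard error. The BeadChip was tested as a term, as an interaction with treatment, as a block and by fitting each BeadChip alone. A total of 35 gene lists were fixed before the data were examined. Of these, 29 had at least 4 measured genes and were tested with camera in limma (preset correlation 0.01), again with an estimated correlation, and with fry. The lymphocyte, neutrophil, adipocyte, adrenal and pancreatic acinar lists had fewer, and the sex-linked list served as a check of the labels. A list score per mouse is the mean over the list's genes of the log2 difference from the saline mean. Single values per mouse, the scores included, were compared by an exact two-sided permutation test over all 924 assignments of 6 and 6 mice, whose smallest possible p is 0.00216.

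Genes were named by a rule fixed before the data were examined: the 12 largest rises and 12 largest falls among called genes, each standing by its probe with the smallest p, with all 6 colistin mice on one side of the saline mean, up to 4 called members of each list or otherwise the 2 members with the smallest p as values only, always Cdkn1a, Havcr1 and Lcn2, and any gene whose called probes disagreed in direction, with predicted names last. Of the genes this rule takes, 2 are not reported here. No gene had called probes of opposite direction. Where a probe was above background on no array of a group, its fold is given as a lower bound: the brighter group's mean against, per array, the higher of the dim probe's value and the lowest detected signal.

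Alternatives covered the background correction, normalization, source of the values, detection filter, BeadChip, replicate number, test and threshold, and each mouse left out in turn. Another 2 settings were chosen after seeing the data: leaving out saline mice 2 and 5 together, and a stromal score (the mean of the endothelial, macrophage and fibroblast list scores) as a covariate. The fit was tested on simulated data with the means and spreads of the 16179 probes and 200 changed probes, 6 arrays against 6. It called 89% of probes changed by 1 on the log2 scale and 44% of those changed by 0.5. Unchanged probes made up 8.9% of its calls, and no called changed probe had the wrong direction. The simulated probes varied independently and no simulated array stood apart, unlike the real arrays, so these rates need not hold for the data. Arrays give no counts, so their number limits the precision.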

Results

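The kidneys of 12 male mice, 6 given saline and 6 given colistin for 72 hours, were profiled on whole-genome expression arrays. Colistin is a polymyxin antibiotic that acts on the outer membrane of Gram-negative bacteria and whose use is limited by kidney toxicity. The comparison asks which kidney transcripts differ after 72 hours of exposure. The arrays detected between 14661 and 16154 probes each, with means of 15406 ± 501 (SD, n = 6) in saline mice and 15446 ± 467 (SD, n = 6) in colistin mice (exact permutation p = 0.877). The 75th percentile of the raw signal was 122 ± 9.40 (SD, n = 6) in saline mice and 131 ± 5.66 (SD, n = 6) in colistin mice (exact permutation p = 0.0433, 0.0877 after adjustment over 6 array measures). As a check of the labels, 1 probe each of the Y-linked genes Ddx3y and Eif2s3y was detected on 12 of 12 arrays, their other probes on 0, and Xist probes on 0.

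Transcripts of dividing cells were higher in colistin mice. The largest rise was that of Prc1 (chromosome 7), which encodes a protein of the mitotic spindle midzone: its log2 signal was 5.76 ± 0.36 (SD, n = 6) in saline mice and 1.76 ± 0.18 (SE) higher in colistin mice, a 3.39-fold rise (adjusted p = 0.000235). The mitotic kinase gene Pbk rose 3.22-fold and Anln, which encodes the cytokinesis protein anillin, 3.08-fold. Mki67, the gene of the proliferation antigen Ki-67, rose 2.58-fold, and Cdc2a (Cdk1, the kinase that drives entry into mitosis) 2.32-fold. The DNA topoisomerase gene Top2a was detected on 0 of 6 saline arrays and 6 of 6 colistin arrays and was at least 1.85-fold higher in colistin mice. Rrm2, a subunit of the enzyme that makes deoxynucleotides, was 2.47-fold higher at the probe that was above background on 2 of 6 saline arrays, and at least 1.81-fold higher at a dimmer one that was above it on none. Uhrf1, which maintains DNA methylation at replication, rose 1.90-fold. Among 16179 probes, limma called 74 changed (68 genes), 52 higher and 22 lower in colistin mice. All 6 colistin mice lay on one side of the saline mean for all 74, but these were chosen by their group difference, so this is no independent check. Of the 46 genes that were higher, 15 belonged to the cell-cycle lists.

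The list of G2 and mitosis genes moved furthest. Of its 18 measured members 12 rose, none fell and 6 did not pass; adjusted over the list alone, 16 were higher and 1 was lower. The member that was lower over the list alone was Kif23 as read by its brightest probe, annotated Knsl5 on the array (-0.31 ± 0.09, SE). This gene, singled out after its values were seen, had other probes at 0.72 ± 0.12 (SE), which was called, and at 0.90 ± 0.19 (SE), which was not. The median change was 0.92 on the log2 scale (camera adjusted p = 5.23e-29, adjusted p = 0.0258 with an estimated correlation), and the list score was higher in 6 of 6 colistin mice than the saline mean (exact permutation p = 0.00216, the smallest possible, 0.0123 after adjustment over the list scores). In this permutation test 7 list scores passed after adjustment. They were those of the G2 and mitosis, G1/S, distal convoluted tubule, fibroblast, glucocorticoid, unfolded protein response and neutrophil lists. The neutrophil score is Lcn2 alone, a gene that is also in the glucocorticoid list. The scores of the tubular injury (0.159), endothelial (0.120), macrophage (0.118), interferon (0.118) and heat shock (0.110) lists did not pass. Cdca3, which promotes entry into mitosis, rose 2.38-fold at its brighter probe, detected on all 12 arrays, and was at least 1.28-fold higher at a dim one, detected on 0 of 6 saline and 6 of 6 colistin arrays. Of 25 G1/S and DNA replication genes 2 rose, Rrm2 and Uhrf1, and 11 were higher adjusted over the list alone. This list's median was 0.29 (adjusted p = 7.33e-12, adjusted p = 0.0615 with an estimated correlation).

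**Figure D1:**
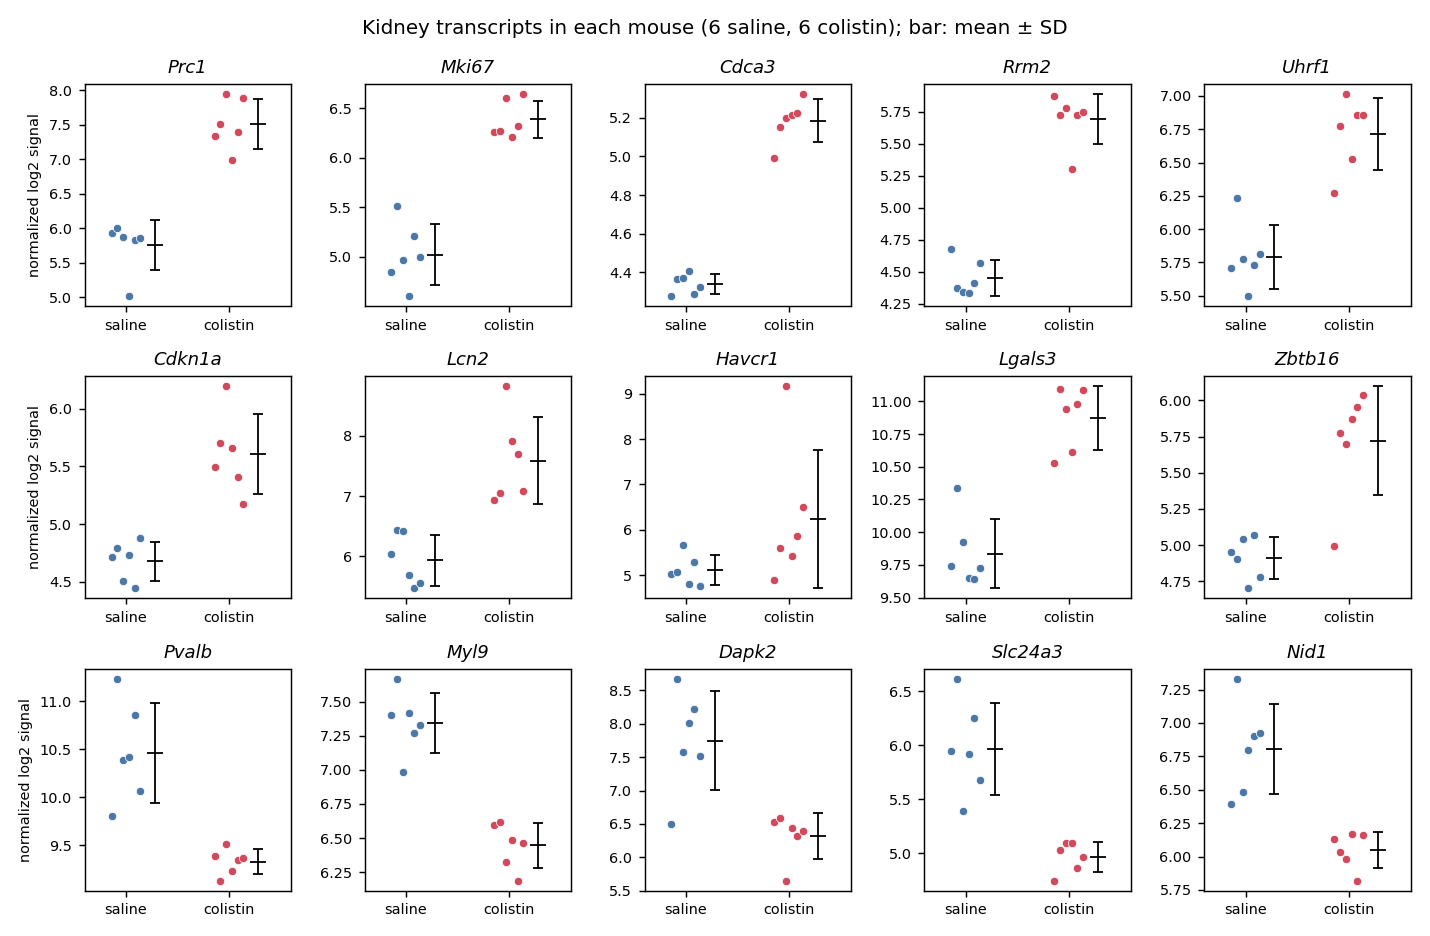
Normalized log2 signal of 15 transcripts in each of the 12 mice, one panel per gene; points are mice (blue saline, red colistin) and the bar beside each group is its mean ± SD (n = 6). Prc1, Mki67, Cdca3 and Rrm2 separate the groups without overlap, while Havcr1 reached 9.16 in colistin mouse 3 alone. Cdca3 and Rrm2 are shown at their dimmer probes, detected on 0 of 6 saline arrays. Prc1, Mki67, Cdca3 and Rrm2 were chosen by their group difference, so their separation is no independent check.

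Some transcripts of tubular injury were higher, while the unfolded protein response and heat shock lists shifted up at the preset correlation with no member called. Lcn2, which encodes the iron-carrier-binding protein NGAL and is a marker of acute kidney injury, rose 3.14-fold (log2 1.65 ± 0.29, SE; adjusted p = 0.0172). Lgals3, which encodes galectin-3, rose 2.05-fold. Havcr1, which encodes the injury molecule KIM-1, did not pass: the log2 fold change of Havcr1 was 1.13 ± 0.53 (SE; adjusted p = 0.456) and 0.55 without colistin mouse 3, whose signal of 9.16 stood above a range of 4.90 to 6.51 in the other colistin mice. Of 21 tubular injury markers 2 rose (3 adjusted over the list alone), with a median of 0.27 (adjusted p = 0.00216, adjusted p = 0.4995 with an estimated correlation). The median log2 fold change of tubular injury markers was 0.20 without colistin mouse 3 and no longer past the threshold (adjusted p = 0.0760). None of 16 unfolded protein response genes passed alone, and the list's median was 0.22 (adjusted p = 0.00189, adjusted p = 0.0839 with an estimated correlation). Its members with the smallest p were Creld2 (log2 0.67 ± 0.23, SE) and Chac1 (0.41 ± 0.15, SE). The median of the unfolded protein response list was 0.13 without saline mice 2 and 5 (camera adjusted p = 0.00326). With the stromal score as a covariate it was 0.08 and the call was lost (camera adjusted p = 0.629). The median log2 fold change of heat shock genes was 0.13 over 13 genes, none called (adjusted p = 0.0364, adjusted p = 0.222 with an estimated correlation). Hspa1a was at 0.58 ± 0.19 (SE) and Dnajb1 at 0.33 ± 0.11 (SE). The heat shock call was also lost with saline mouse 1, 3 or 6 or colistin mouse 2 or 3 left out, with adjusted p = 0.0645 at saline mouse 1 and 0.206 at saline mouse 3.

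Cdkn1a, which encodes the cell-cycle inhibitor p21, rose 1.90-fold (log2 0.93 ± 0.15, SE; adjusted p = 0.00869; higher in 6 of 6 colistin mice). Its probe was above background on 1 of 6 saline arrays and 6 of 6 colistin arrays. A second Cdkn1a probe lay at 0.25 ± 0.13 (SE) and was not called (adjusted p = 0.487). Cdkn1a was the 1 called member of the 20 measured p53 targets, whose median was -0.03 (adjusted p = 0.992); adjusted over the list alone, 1 was higher and 1 lower. The glucocorticoid and fasting responsive genes had a median of 0.39 (adjusted p = 4.00e-05, adjusted p = 0.0615 with an estimated correlation), and 3 of 15 rose, 4 adjusted over the list alone. The 3 were Lcn2, Cdkn1a and Zbtb16, a transcription factor induced by glucocorticoids, which rose 1.76-fold.

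Other large rises were those of the transcripts named EG638695 (2.97-fold) and E030010A14Rik (Tmem252, 2.01-fold). The largest fall was that of Dapk2, which encodes a calmodulin-regulated kinase, at 2.69-fold lower (log2 -1.43 ± 0.28, SE; adjusted p = 0.0392). C1qtnf2 fell 2.20-fold. Pvalb, which encodes the calcium-binding protein parvalbumin of the early distal convoluted tubule, fell 2.19-fold (adjusted p = 0.0135). The carboxypeptidase gene Cpm was 2.02-fold lower and Slc24a3, which encodes a sodium, calcium and potassium exchanger, 2.00-fold lower. Among other genes, Myl9 (smooth muscle myosin light chain) fell 1.87-fold, Loxl1 (an elastin crosslinking enzyme) 1.85-fold, Nid1 (the basement membrane protein nidogen) 1.69-fold, Mrvi1 1.64-fold, Ltbp4 (a binding protein of latent TGF beta) 1.63-fold and Tpst1 1.62-fold. Cpm, Myl9, Nid1 and Ltbp4 each had 2 kept probes, both lower in colistin mice, of which only 1 was called. The transcript 1200009O22Rik (Tril) was 2.16-fold lower. With the BeadChip as a block the calls of Dapk2 (adjusted p = 0.0643), C1qtnf2 (0.0574), Ltbp4 (0.0648) and 1200009O22Rik (0.0566) were lost.

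Lists of endothelial, macrophage, fibroblast and interferon genes were lower. Of 13 endothelial markers, 14 macrophage markers, 14 fibroblast and matrix genes and 15 interferon response genes, none passed alone, and 6, 2, 3 and 0 were lower adjusted over the list alone. The endothelial median was -0.43 (adjusted p = 6.41e-07, adjusted p = 0.231 with an estimated correlation), with Cd34 at -0.52 ± 0.15 (SE) and Cdh5 at -0.45 ± 0.14 (SE). Saline mouse 1, with an endothelial score of -0.80, lay below all 6 colistin mice (-0.54 to -0.24). The macrophage median was -0.41 (adjusted p = 1.00e-05, adjusted p = 0.226 with an estimated correlation), although its member Csf1r was at 0.15 ± 0.15 (SE). A dimmer Csf1r probe was above background on 0 of 6 saline and 4 of 6 colistin arrays, so no fold is given, and it was not called (adjusted p = 0.235). The complement gene C1qc was at -0.47 ± 0.13 (SE). The fibroblast and matrix median was -0.23 (adjusted p = 0.00176, adjusted p = 0.0615 with an estimated correlation), with Pdgfrb at -0.70 ± 0.16 (SE) and Dcn at -0.78 ± 0.21 (SE). The interferon median was -0.28 (adjusted p = 3.96e-05, adjusted p = 0.381 with an estimated correlation), with Rsad2 at -0.76 ± 0.23 (SE) and Psmb9 at -0.48 ± 0.17 (SE). Saline mice differed among themselves in these transcripts, and saline mice 2 and 5 stood apart from the other arrays. Saline mouse 2 had the highest value on the first principal component (64.3, against at most 28.6 elsewhere; 49.3% of the variance), and saline mouse 5 had the dimmest array (95th percentile of the raw signal 475, against 752 or more elsewhere). Without these 2 mice the interferon median was -0.07, the macrophage median -0.24, the endothelial median -0.33 and the fibroblast median -0.20, each past the threshold with the preset correlation and not with an estimated one (adjusted p = 0.378, 0.325, 0.342 and 0.0573). Saline mouse 1 lay at the other end of the first principal component (-27.0, the lowest value). Without saline mouse 1 the medians were -0.40 (interferon), -0.47 (macrophage), -0.58 (endothelial) and -0.23 (fibroblast). Each passed with the preset correlation, the only one used in that setting. The stromal score, the mean of the endothelial, macrophage and fibroblast scores, was 0.33 in saline mouse 2 and -0.32 in saline mouse 1, against -0.49 to -0.18 in the colistin mice (exact permutation p = 0.0152, 0.0877 after adjustment over 6 array measures). With that score as a covariate, 62 probes were called, and of the 74 called without it 29 of the higher and 0 of the lower remained called. The score was made from the same arrays and was itself lower in colistin mice. Fitting it therefore takes out part of any fall, and the lost calls do not show the cause of the falls.

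**Figure D2:**
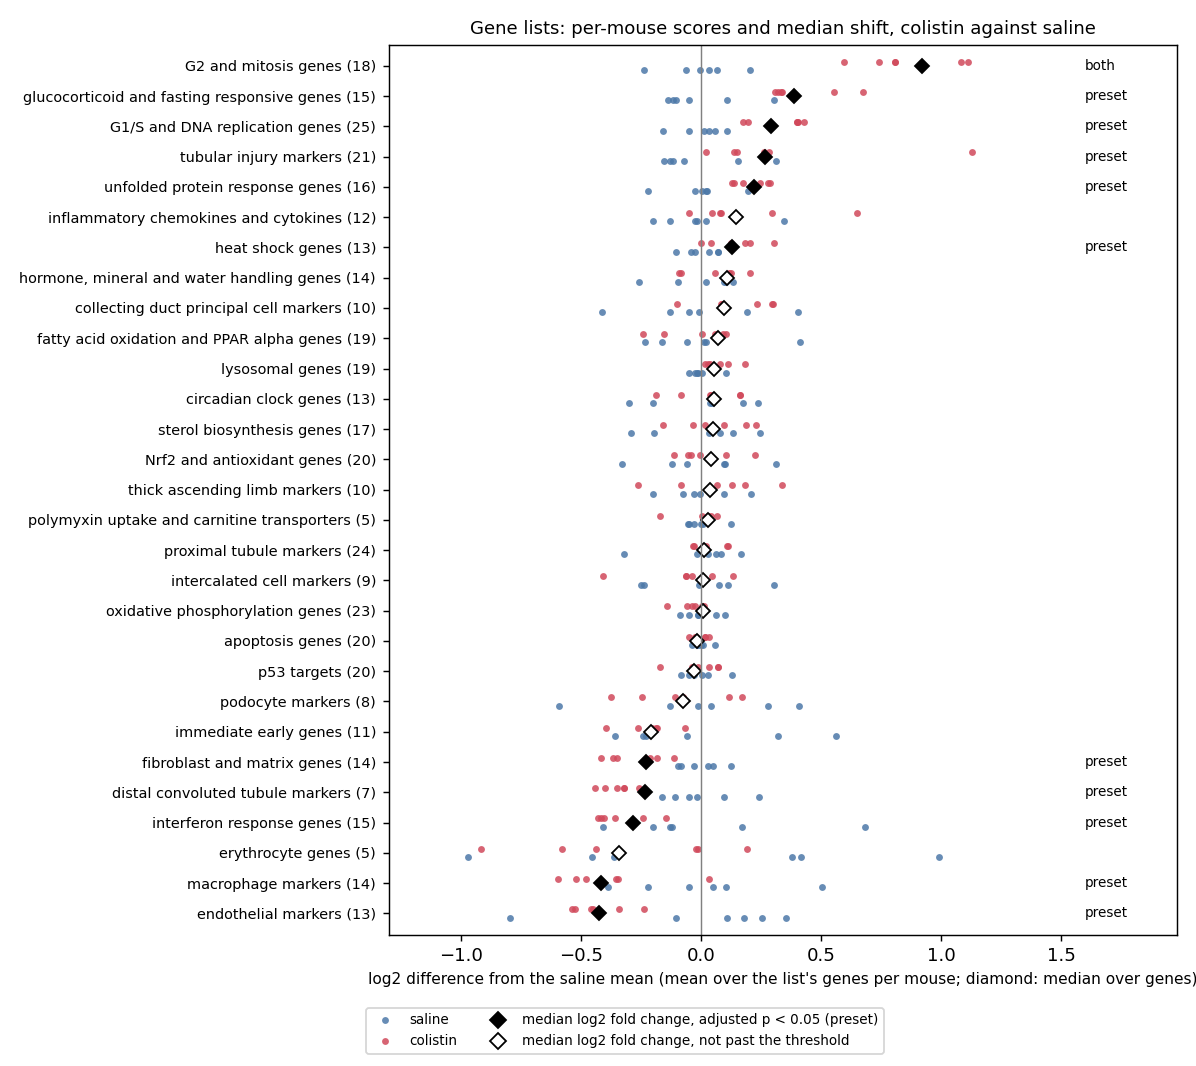
Shift of the 29 tested gene lists, with the number of measured genes in brackets; points are per-mouse list scores (blue saline, red colistin, log2 difference from the saline mean) and diamonds the median log2 fold change over the list's genes, filled where camera's adjusted p passed with the preset correlation. The words at the right mark lists that passed with the preset correlation or with both; G2 and mitosis genes, at 0.92, was the list that passed with both.

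Markers of most nephron segments gave no list call. The proximal tubule list had a median of 0.01 over 24 genes (adjusted p = 0.839), with Slc4a4 at -0.12 ± 0.09 (SE) and Aqp1 at 0.22 ± 0.14 (SE) at the probes that entered the list. Their probes with the smallest p lay at -0.52 ± 0.16 (SE; adjusted p = 0.234) for Slc4a4 and 0.28 ± 0.11 (SE; adjusted p = 0.394) for Aqp1. The 5 measured polymyxin uptake and carnitine transporters had a median of 0.03, the thick ascending limb 0.04, collecting duct principal cells 0.10, intercalated cells 0.01 and podocytes -0.07. The distal convoluted tubule list was lower, with a median of -0.23 over 7 genes (adjusted p = 0.00278, adjusted p = 0.0839 with an estimated correlation). Its called member was Pvalb, and 2 were lower adjusted over the list alone. The list score, which includes Pvalb, was below the saline mean in all 6 colistin mice. Its exact permutation p was 0.00216 (0.0123 after adjustment over the list scores), and the list passed in fry (adjusted p = 0.0112). The median log2 fold change of distal convoluted tubule markers was -0.13 without saline mouse 3, with the call lost (adjusted p = 0.0535). Without saline mouse 1 the median of this list was -0.15 (camera adjusted p = 0.00949). It was -0.45 without saline mice 2 and 5 (camera adjusted p = 7.73e-06, adjusted p = 0.0511 with an estimated correlation). The lists of apoptosis (median -0.02), Nrf2 and antioxidant (0.04), fatty acid oxidation and PPAR alpha (0.07), oxidative phosphorylation (0.01), sterol biosynthesis (0.05), lysosomal (0.06), circadian clock (0.05), hormone, mineral and water handling (0.11), inflammatory chemokine and cytokine (0.15), immediate early (-0.21) and erythrocyte genes (-0.34) did not pass. The chemokine and the immediate early lists lay near the threshold (adjusted p = 0.0750 and 0.0674), and each passed in 7 of 26 alternatives. The median log2 fold change of inflammatory chemokines and cytokines was 0.17 without saline mice 2 and 5 (adjusted p = 0.000635), and it also passed without saline mouse 2 or colistin mouse 2, 4 or 5. The median log2 fold change of immediate early genes was -0.23 on BeadChip 1 (adjusted p = 0.00332), and it passed without saline mouse 4 or 5 or colistin mouse 2. The mean lay below 0 while the median lay above it for fatty acid oxidation (-0.02), oxidative phosphorylation (-0.04) and intercalated cell genes (-0.06). The antioxidant gene Hmox1 was at 1.16 ± 0.45 (SE; adjusted p = 0.379; the log2 fold change of Hmox1 was 0.75 without colistin mouse 5) and the chemokine gene Cxcl10 at 0.59 ± 0.13 (SE; adjusted p = 0.0623). Among the lists too small to test, Cd52 (lymphocytes), Car3 and Cfd (adipocytes), Akr1b7 (adrenal) and Ela1 (Cela1, pancreas) were not called, and Lcn2 was the 1 measured gene of the neutrophil list. The signal of Cfd, an adipocyte transcript, was 11.6 in saline mouse 1 and at most 9.16 in the others.

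The groups were compared within each BeadChip to see whether the colistin effect held on both. Of all kept probes, 63.4% had the same direction on each; so did the 74 called probes, which were chosen by their effect over both. Lists were tested on each BeadChip with the preset correlation alone. G2 and mitosis genes had a median of 0.74 on BeadChip 1 and 1.05 on BeadChip 2, each past the threshold. Endothelial markers were at -0.19 and -0.60, macrophage markers at -0.41 and -0.31 and interferon genes at -0.32 and -0.27, and all 3 passed on each BeadChip. Glucocorticoid and fasting genes (0.16 and 0.54) and G1/S genes (0.36 and 0.21) passed on each as well. Over all mice, the endothelial, macrophage, interferon, glucocorticoid and G1/S lists had not passed with an estimated correlation. Their passes on both BeadChips are therefore no firm check. Over all mice, G1/S (adjusted p = 0.00371) and glucocorticoid genes (0.0112) passed in fry. Endothelial (0.0950), macrophage (0.0926) and interferon genes (0.208) did not pass in fry. The exact permutation test of the list scores divided these lists in the same way. Tubular injury markers passed on BeadChip 2 (0.50) and not on BeadChip 1 (0.06). Fibroblast genes passed on BeadChip 1 (-0.23) and not on BeadChip 2 (-0.14), as did the unfolded protein response (0.23 and 0.13). The distal convoluted tubule list was at -0.46 on BeadChip 1 and 0.05 on BeadChip 2, and heat shock genes passed on neither (0.17 and 0.21). The distal convoluted tubule score, a mean over genes that includes Pvalb, was nevertheless lower in colistin mice on BeadChip 2. There it was -0.32 to -0.26 in colistin mice and -0.16 to -0.02 in saline mice. These differences between BeadChips were not tested for lists. Across probes, which are not independent replicates, log2 fold changes of the BeadChips had a Pearson r of 0.47 and a Spearman rho of 0.41. With the BeadChip as a block 65 probes were called, 64 of them among the 74, and the same 11 lists passed with the preset correlation.

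**Figure D3:**
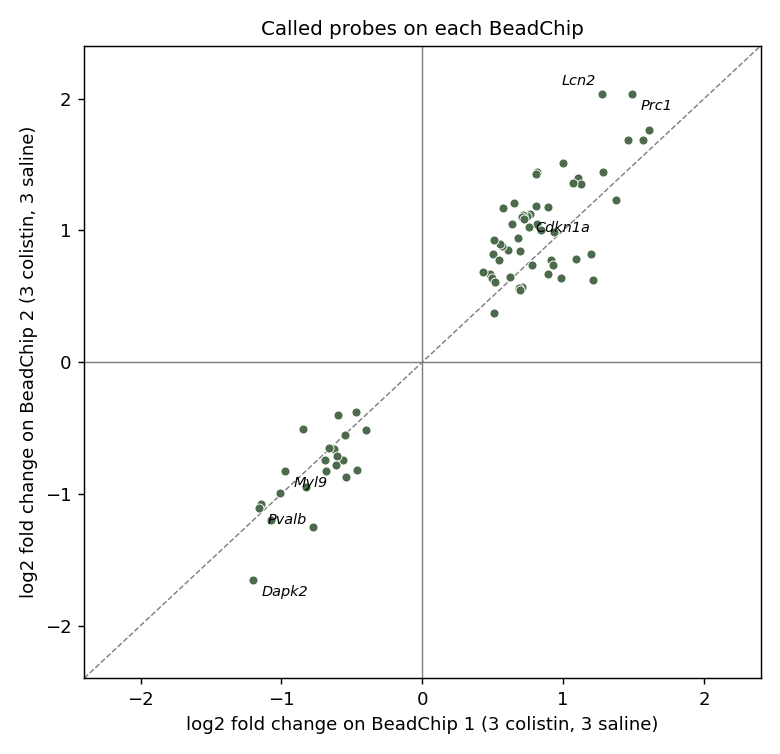
Log2 fold change of the 74 called probes on BeadChip 1 (horizontal axis) and BeadChip 2 (vertical axis), each from 3 colistin and 3 saline mice; the dashed line marks equal values. The probes were chosen by their effect over both BeadChips, so matching directions are no independent check.

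Fitted alone, BeadChip 1 gave 0 called probes in limma (337 at an unadjusted p under 0.05) and BeadChip 2 gave 304 (106 higher, 198 lower; 3362 at an unadjusted p under 0.05). The interaction of BeadChip and treatment in limma gave 0 probes, with 409 at an unadjusted p under 0.05. The BeadChips themselves differed at 0 probes, with 804 at an unadjusted p under 0.05. The count of called probes rested on single mice: it was 329 (106 higher, 223 lower) without saline mouse 1, and 37 without saline mouse 4, 47 without saline mouse 6, and 45, 40, 44 and 48 without colistin mice 2, 3, 5 and 6. Without saline mice 2 and 5 together, whose arrays stood apart from the rest, 91 probes were called (73 higher, 18 lower), 58 of them among the 74: 48 of the 52 rises and 10 of the 22 falls. The lost falls included Dapk2 (adjusted p = 0.0705), Cpm (0.0916), Ltbp4 (0.115) and 1200009O22Rik (0.0629). A core of 37 probes (32 genes; 32 probes higher, 5 lower) was called in the fit of all mice and in each of the 12 fits with a mouse left out. Among the named genes this core held Prc1, Pbk, Anln, Mki67, Top2a, Rrm2, Cdca3, Cdc2a, Uhrf1, Cdkn1a, Lgals3 and EG638695, and among the falls Pvalb, Slc24a3, Myl9 and Mrvi1, while the calls of Lcn2, Zbtb16, Dapk2, C1qtnf2, Cpm, Loxl1, Nid1, Ltbp4, Tpst1, E030010A14Rik and 1200009O22Rik were lost in at least 1 of these fits.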

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

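The tests of saline mice 2 and 5, of perirenal fat, of the share of cortex or medulla, of the mitosis list over other splits and of the interaction with the treatment effect removed were chosen after the values were seen, and the leukocyte, smooth muscle and injury tests after the patterns they address. A total of 228 groups of 6 values were examined for a mouse far from the others, and 18 held one, against 11.4 that chance gives at 1 in 20. Among array measures, the 95th percentile of the raw signal was 475.2 in saline mouse 5 and 752.3 to 864.0 in the other saline mice, and the first principal component was 0.709 in colistin mouse 6 against -14.60 to -11.49 in the other colistin mice. The tubular injury score was 1.128 in colistin mouse 3 and 0.02 to 0.28 in the other colistin mice. The polymyxin uptake score was 0.1244 in saline mouse 6 and -0.1702 in colistin mouse 4, the intercalated cell score was -0.4059 in colistin mouse 6, and the lysosomal score was 0.1024 in saline mouse 1. Among named genes, log2 signals far from the rest of the group were 5.023 for Prc1 in saline mouse 4, 5.304 for Rrm2 in colistin mouse 4, 5.648 for Dapk2 in colistin mouse 3, 8.34 for Slc4a1 and 4.475 for Csf1r in colistin mouse 6, 4.798 for Cdh5 in saline mouse 1, 10.33 for Dci in colistin mouse 2 and 4.995 for Zbtb16 in colistin mouse 1. The transcript 2010004A03Rik (Il34) was at 6.221 in saline mouse 1 and at 6.377 in colistin mouse 3. Cfd was at 11.62 in saline mouse 1 and 4.36 to 6.22 in the other saline mice.

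The rise of G2 and mitosis genes was set against chance, atypical saline arrays and leukocytes. Of 100 splits of the 12 mice into 6 and 6, the real one included, 1 gave a median shift of this list as large as 0.92 (the highest of the others was 0.80), and 1 gave as many as 74 called probes (the highest of the others was 2). Chance is therefore unlikely for both, though with 100 splits the share cannot lie below 1 in 100. The list was picked after its shift was seen, and the largest shift over all lists was not compared. Without saline mice 2 and 5 the list's median was 0.99 (adjusted p = 0.0240 with an estimated correlation), which argues against those arrays as its source. Dividing leukocytes stay open as a source: pan-leukocyte genes outside the fixed lists had a median of -0.0277 over 9 measured genes (camera adjusted p = 0.261), from Coro1a at -0.62 to Hcls1 at 0.10; a median below 0, set beforehand as the bound against leukocytes, was met, but by less than the spread of the genes, and the need for a camera call was added after the value was seen. Dividing injured tubule cells may carry the signal, since among the 6 colistin mice the mitosis and tubular injury scores had a Pearson r of 0.7246 (exact permutation p = 0.05) and a Spearman rho of 0.60 (exact permutation p = 0.242), but r was 0.30 without the 2 mice farthest from the median, so the relation rests on those mice and decides nothing.

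The lower endothelial, macrophage, fibroblast and interferon lists were set against the same saline arrays and against the makeup of the tissue pieces. Without saline mice 2 and 5 the endothelial median was -0.33 and the macrophage median -0.24, each past the threshold with the preset correlation but not with an estimated one (camera adjusted p = 0.342 and 0.325). With all mice these lists had not passed with an estimated correlation either (0.231 and 0.226). That failure therefore does not bear on those arrays, which stay open as a source. The interferon median moved from -0.28 to -0.0703 (camera adjusted p = 0.0185, adjusted p = 0.378 with an estimated correlation). Among the saline mice, mice 2 and 5 had the highest interferon (0.68 and 0.17), endothelial (0.36 and 0.25) and macrophage scores (0.50 and 0.10). Leaving them out shrinks such a fall whatever its cause, so the smaller medians cannot decide whether those arrays were its source. Leaving out saline mouse 1 instead gave medians of -0.40 (interferon), -0.58 (endothelial) and -0.47 (macrophage). A larger share of cortex or medulla stays open. The thick ascending limb score minus the proximal tubule score differed between groups by 0.0302 ± 0.139 (SE, exact permutation p = 0.820). This test replaced a first one on the list medians after its output was seen. The difference plus 2 standard errors lay below the size of the endothelial and macrophage shifts, but not below the smaller fibroblast and interferon shifts. How far a regional share would move these genes was not measured, so the test cannot decide. It also left out the distal convoluted tubule list, whose median was -0.23. A smaller share of vessels and stroma in the colistin pieces is a candidate explanation that the data left standing, since vascular smooth muscle and mesangial genes outside the fixed lists were lower as well, with a median of -0.26 over 11 genes (camera adjusted p = 0.00446, adjusted p = 0.0430 with an estimated correlation), 9 of them lower (Rgs5 at -0.62) and 2 higher (Smtn at 0.30), and of -0.24 without saline mouse 1 (adjusted p = 0.0258). These p values were adjusted over the lists added for such tests alone, not together with the 29 fixed lists. The smooth muscle list was not refitted without saline mice 2 and 5. A loss of vessel and stroma transcripts per cell under colistin was not tested. Of 100 splits of the mice 9 gave as many as 11 lists past the threshold (the highest of the others was 13), so chance cannot be excluded for the number of shifted lists.

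Saline mouse 1 stood apart in transcripts of fat and smooth muscle. Of 7 adipocyte marker probes detected on any array, 5 had their highest signal in this mouse; Cfd was at 11.62, Adipoq at 7.42 (at most 6.17 elsewhere) and Car3 at 7.14 (at most 5.52 elsewhere), and the 2nd-highest Cfd and Adipoq signals were those of colistin mouse 3. Perirenal fat in the tissue piece is a candidate explanation. Smooth muscle transcripts, chosen after their values were seen, were highest there too, with Actg2 at 6.86 and Myh11 at 6.87 against at most 4.89 elsewhere for either, so ureter or vessel wall in the piece stays open, and no biological explanation was tested since saline mice form 1 group. Without this mouse 329 probes were called, the 74 among them.

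For the BeadChips, 57 of 100 reassignments of treatment within BeadChips, made after the fitted treatment effect had been removed, gave at least the 409 probes at an unadjusted p under 0.05 for the interaction (the highest of the others was 4501), and 27 of 100 reassignments of the BeadChip within groups gave at least 804 (the highest of the others was 3572), so chance cannot be excluded for either. Some reassignments gave several times the real counts, and the cause was not tested. BeadChip 1 alone gave 0 called probes in 10 of its 10 splits of 3 and 3 mice, and BeadChip 2 alone gave 304 in 1 of 10 (the highest of the others was 0); 10 splits are too few for a share under 0.05.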

How the results depend on the processing

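The settings without saline mice 2 and 5 and with the stromal covariate were chosen after the data were seen. The count of 74 called probes (70.3% higher) fell to 25 without background correction (92.0% higher), 43 with normexp on the signals alone (81.4% higher), 7 with the gene-level raw table, 33 with no detection filter, which tests 45281 probes, 27 on probes detected on all 12 arrays and 0 on BeadChip 1 alone. It rose to 304 on BeadChip 2 alone, 470 with array weights (42.1% higher), 139 at an adjusted p under 0.1 and 209 at an unadjusted p under 0.01 with 1.5-fold; where no construction is named, the cause was not tested. With 1 mouse left out it ranged from 37 to 329. With replicate number as a block 36 probes were called; the numbers do not pair the mice, since 1 of 6 same-numbered pairs correlated above 0.1 and 0 of 6 saline mice correlated best with their own number. Cyclic loess gave 73, median scaling 53 and the authors' normalized probe values 75 called probes. No called probe changed direction under any alternative with the same probes. The called probes were chosen by their group difference on the same arrays, so this is no independent check. The number of shifted lists, 11, moved to 1 with an estimated correlation and 6 with fry, and ranged from 9 to 12 with 1 mouse left out. No probe passed for the interaction or for the BeadChips in any alternative. With the stromal covariate, the medians of 14 of 29 lists changed sign. Of lists called with or without it, 6 took the other direction in camera: proximal tubule markers (median -0.21), Nrf2 and antioxidant genes (-0.16) and sterol biosynthesis genes (-0.13) were called lower, and endothelial (0.0760), macrophage (0.0940) and interferon genes (0.21) lay above 0, uncalled; this follows in part from the score's construction from the endothelial, macrophage and fibroblast lists, and for the others the cause was not tested. Across the other list values, 696 kept their side of the threshold, 33 lost a call and 19 gained one; for named genes 2290 kept it, 210 lost a call, 41 gained one and none changed direction between a call and its alternative, while uncalled genes changed sign in some. Signal over background limits the dim probes: the fold of Top2a and those of the dimmer probes of Rrm2 and Cdca3 are lower bounds.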

Other observations

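The tests on Cdkn1a were chosen after the values were seen, and the urothelium test after the rises it addresses. Several called genes that the naming rule did not take are given here, chosen after their values were seen. The spindle checkpoint gene Mad2l1 rose by 0.83 on the log2 scale and the tubulin gene Tubb2b by 0.87, each at its called probe with the smallest p. The kinesin gene Kif4, the recombination gene Rad54l and the cornified envelope gene Sprr2g also rose; their probes were above background on 0 of 6 saline arrays and on 6, 6 and 4 colistin arrays, so no fold is given. The integrin gene Itga6 rose by 0.66. Among the falls were Hspg2 (perlecan, -0.66), the matrix protease gene Mmp2 (-0.64), the procollagen-processing gene Adamts2 (-0.68; adjusted p = 0.0656 with the BeadChip as a block) and Des (desmin, -0.55). No enrichment was tested for these genes. Of the 22 genes that were lower, 1 belonged to a list fixed beforehand.

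More pelvis or papilla lining in the colistin tissue pieces was a hypothesis for the rises of Lgals3 and Sprr2g, and its test did not bear it out. A list of urothelium and papilla lining genes that leaves these genes out had a median of -0.0539 over 12 genes, 6 of them higher (camera adjusted p = 0.478). Members went both ways, from Sprr1a at 0.72 ± 0.16 (SE; adjusted p = 0.0684) to Ly6d at -0.71 ± 0.33 (SE; adjusted p = 0.458). The median met the bound set beforehand against the hypothesis, a value below 0, but by less than the spread of the genes, so it does not exclude it either.

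The rise of Cdkn1a raises the hypotheses of a p53 response and of a glucocorticoid response. The p53 targets without Cdkn1a had a median of -0.0311 over 19 genes (camera adjusted p = 0.478), from Sesn2 at 0.51 ± 0.18 (SE) to Ccnd2 at -0.88 ± 0.26 (SE), neither called, so a p53 response of a few targets stays open. The glucocorticoid and fasting genes without Cdkn1a and Lcn2 had a median of 0.29 over 13 genes, 10 of them higher (camera adjusted p = 0.00446, adjusted p = 0.141 with an estimated correlation), and of 0.17 without saline mouse 1 (camera adjusted p = 0.0258). A response to glucocorticoids or to lower food intake could give this shift. However, the p values were adjusted over the added lists alone, and the whole list had been seen to shift before the test. Zbtb16 was its called member; Fkbp5 was at 0.98 ± 0.24 (SE; adjusted p = 0.120) and Per1 at -0.05 ± 0.22 (SE). Neither hormone levels nor food intake were measured in the data used here.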
